A study of Mus musculus with 16 samples.

How the data were processed

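RNA from sorted CD4+ T cells of male mice 6 weeks old was hybridized to Affymetrix Mouse Gene 1.0 ST arrays, 16 in all. There were 2 in each of 8 groups formed by cell type (Treg or Tconv), Foxp3 reporter allele (fusion or ires) and background (B6 or NOD). Per the submitters' processing notes, the authors summarised the probe sets with Affymetrix Power Tools and RMA, and the deposited values are intensities on a linear scale. The versions of these tools and the genome build behind the annotation are not given in the sources used here. The quartiles of the deposited intensities differed between arrays, with medians between 86.7 and 99.0. No scanner files were used, so the background correction could not be varied.

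The intensities were turned into log2 values without a pseudocount. The table held 25108 probe sets, of which 21157 carried exactly 1 gene symbol in the platform's table, 1341 carried several and 2610 none. The 21157 covered 19531 genes, 906 of them with more than 1 probe set. Each gene was represented by its probe set with the highest mean over the 16 arrays. Genes above the 40th percentile of all values, log2 6.06, on at least 2 arrays were tested, which left 12798. A reference annotation of assembly GRCm38.p6 was used only to check names and for the order of neighbouring genes. Sequence differences between the strains and the arrays' probes were not examined.

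A linear model with 1 mean per group was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (8 residual and 9.80 prior degrees of freedom). The tests were two-sided. The contrasts were Treg against Tconv over the 4 mouse lines, fusion against ires in Treg (mean of both backgrounds, B6, NOD, and NOD minus B6), fusion against ires in Tconv, the allele effect in Treg minus that in Tconv, NOD against B6 in Treg and in Tconv, and the difference between these. Each contrast's p-values were adjusted by the Benjamini-Hochberg method over the 12798 genes, and 0.05 was the threshold. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

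The following choices were made before the data were examined: the contrasts, the filter, the tests, 17 gene lists and the rule for naming genes. The lists were Treg-high genes, Tconv-high genes, effector Treg and IRF4-linked genes, HIF-1 and hypoxia target genes, IL-2 and STAT5 target genes, cell cycle genes, and interferon response genes. Others were immediate-early and dissociation genes, helper cytokines and lineage regulators, naive and central T cell genes, TGF-beta response genes, and genes of diabetes susceptibility (Idd) regions. Marker lists were those of B cells and plasma cells, myeloid cells, dendritic cells and MHC class II, CD8 T, NK and gamma-delta T cells, and red cells and platelets. They were written from general knowledge, the effector list also with knowledge that IRF4 had been of interest in this line. The Treg-high and effector lists share 11 tested genes, and the Tconv-high and naive lists share 6. With the Treg-high list, the IL-2 and STAT5 list shares 5 and the Idd list 4. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals, adjusted over the 17 lists of a contrast. Named genes were the 8 highest and 8 lowest called per contrast, in pooled contrasts only those with the same sign in each part, up to 4 called genes per list, and always Foxp3, Il2ra, Ctla4, Ikzf2, Irf4, Prdm1, Hif1a and Entpd1. Symbols of the form Gm plus a number, ending in Rik or starting with LOC, Mir or Snor, and antigen receptor segments were counted but not named. An exception is Gm7265, given because it was called in both backgrounds. The text leaves out many of the genes that the rule names.

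Alternatives were no filter and a stricter filter at the 60th percentile, centring each array on its median, quantile normalization, limma with trend and robust variances, array weights, the mean of a gene's probe sets, every probe set on its own, a fit of only the groups compared, replicate blocks, leaving out each array in turn, and for the lists the estimated correlation and limma's fry. A fit with each array's interquartile range as a covariate was added after the data were seen. The fit and the list test were tested on simulated data with 200 changed genes among 12798. For fusion against ires in Treg over both backgrounds, 71.6% of genes changed by 0.5 (log2) and 98.5% of those changed by 1 were recovered. For the same comparison in B6 alone, 41.8% and 86.6% were recovered. Of 50 simulated data sets with no effect, 2 had any list called. Genes varied independently in the simulation, so it does not check the preset correlation where genes vary together. The correlation estimated from the arrays ran from -0.0592 (CD8 T, NK and gamma-delta T cell markers) to 0.834 (interferon response genes).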

Results

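Gene expression was measured in CD4+ T cells sorted from the spleens of male mice 6 weeks old. Regulatory T cells (Treg), which carry the transcription factor Foxp3, were taken as GFP-positive cells, and conventional T cells (Tconv) as GFP-negative cells. The mice carried 1 of 2 reporter alleles of Foxp3. In the first, called fusion here, GFP is joined to the Foxp3 protein itself. In the second, called ires here, GFP is translated separately from the same transcript and the protein is left as it is. Both alleles were studied on the C57BL/6 (B6) background and on the NOD background, a strain that develops autoimmune diabetes. Cell type, allele and background made 8 groups with 2 arrays each, 16 arrays in all. The labels number the arrays of a group 1 and 2 and do not say whether these came from separate mice or from pools, so the p-values below measure the spread between these arrays, which may be technical. The median intensity per array lay between 86.7 and 99.0, and the number of arrays limits the precision. The SD of the log2 difference between the 2 arrays of a group lay between 0.18 and 0.25 over the tested genes. Differences are given as log2 values ± SE from a linear model of all 16 arrays, with Benjamini-Hochberg adjusted p, and a gene was called at an adjusted p under 0.05.

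**Figure D1:**
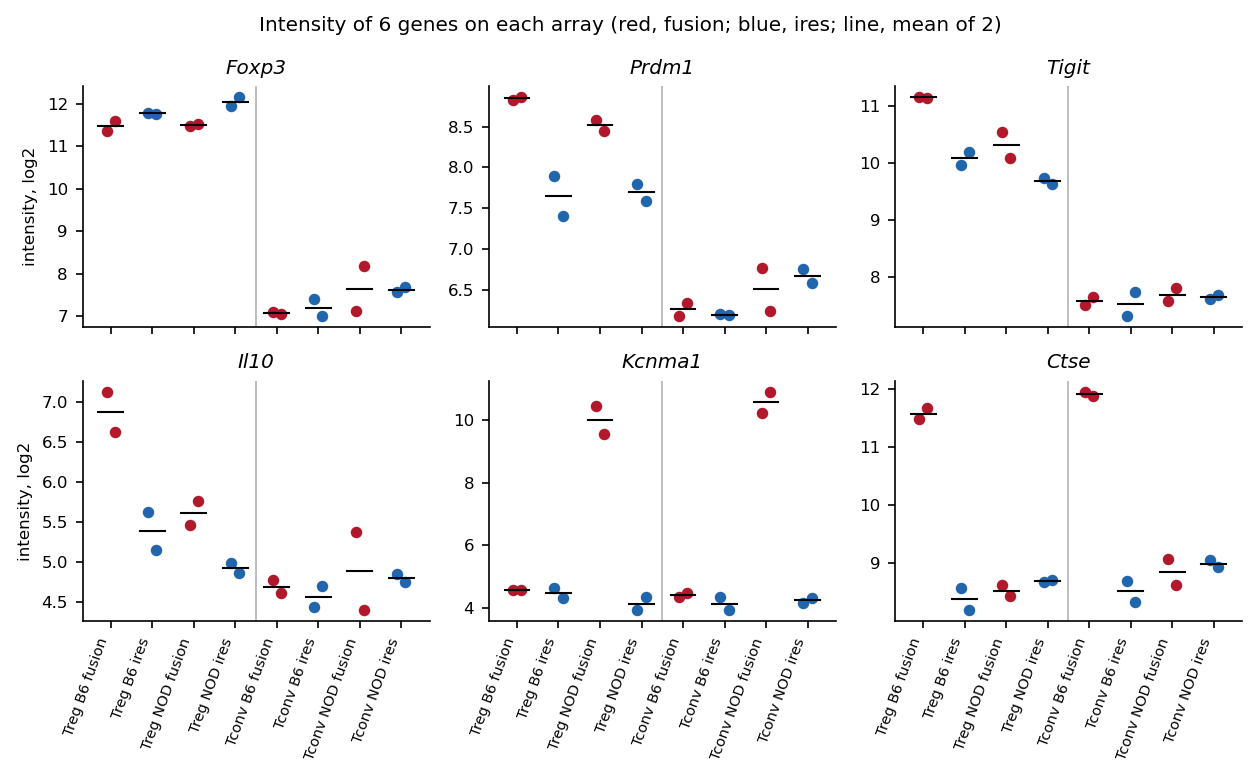
Log2 intensity of Foxp3, Prdm1, Tigit, Il10, Kcnma1 and Ctse on each of the 16 arrays, with 1 point per array (red, fusion; blue, ires) and a line at the mean of the 2 arrays of a group. Foxp3 lay between 11.37 and 12.16 on the Treg arrays and between 7.01 and 8.18 on the Tconv arrays, and Kcnma1 was near 10 only in NOD fusion cells, of both cell types.

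The comparison of Treg with Tconv over the 4 mouse lines asked what sets the sorted populations apart. Foxp3 (probe set 10598292) was higher in Treg by 4.31 ± 0.11 (adjusted p = 1.34e-15), with all 8 Treg arrays above all 8 Tconv arrays. Il2ra, the high-affinity chain of the interleukin-2 receptor, was higher by 5.29 ± 0.15, and the inhibitory receptor Ctla4 by 4.27 ± 0.12. Lrrc32, which holds latent TGF-beta at the Treg surface, rose by 4.40 ± 0.08, and the transcription factor Ikzf2 by 3.74 ± 0.09. Pde3b, a phosphodiesterase repressed in Treg, was lower by -4.62 ± 0.08, and Dapl1 and Igfbp4 by -3.67 ± 0.08 and -3.00 ± 0.09.

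Of 12798 genes tested, 3664 were called between Treg and Tconv, 2138 higher and 1526 lower in Treg, and 249 and 83 of them by at least 2-fold. The split depended on the scaling of the arrays, with 1717 higher and 1714 lower after centring each array on its median, and 2024 higher and 2434 lower after quantile normalization. All 35 tested genes of the Treg-high list rose (35 adjusted over the list alone), with a median of 2.65, and all 13 of the Tconv-high list fell (13 adjusted over the list alone), with a median of -1.52. The list test, camera, called both (adjusted p = 2.43e-54 and 2.49e-23; adjusted p = 0.000712 and 0.0138 with an estimated correlation). Of 25 effector Treg and IRF4-linked genes, 24 rose and 1 fell, adjusted over the list alone likewise (median 1.75, adjusted p = 1.61e-28; adjusted p = 0.00288 with an estimated correlation). Examples were Ccr8 (3.01 ± 0.08), Tigit (2.71 ± 0.08), Tnfrsf9 (2.80 ± 0.07) and Itgae (3.46 ± 0.10). Irf4 itself rose by 1.75 ± 0.09 and Prdm1, which encodes Blimp-1, by 1.77 ± 0.08.

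Among 17 IL-2 and STAT5 target genes 12 rose and 3 fell (12 and 3 adjusted over the list alone; median 1.04, adjusted p = 9.01e-09; adjusted p = 0.0411 with an estimated correlation). Socs2 rose by 3.23 ± 0.11 and Tnfrsf18 by 1.94 ± 0.06, both of them also members of the Treg-high list. A second probe set of Socs2, with a mean of 7.13, differed by only 1.1. The list of genes in diabetes susceptibility (Idd) regions had 9 members up and 3 down (9 and 3 adjusted over the list alone; median 0.56, adjusted p = 4.40e-07; adjusted p = 0.0382 with an estimated correlation). Of 30 cell cycle genes 22 rose and none fell (24 and 1 adjusted over the list alone; median 0.49, adjusted p = 2.41e-10; adjusted p = 0.107 with an estimated correlation), among them Mki67 at 1.48 ± 0.11. Immediate-early genes, which cell isolation can induce, had 17 up and 2 down (18 and 4 adjusted over the list alone; median 0.26, adjusted p = 6.93e-06; adjusted p = 0.107 with an estimated correlation), with Nr4a1 at 1.24 ± 0.08. Naive and central T cell genes had 10 down and 2 up (10 and 2 adjusted over the list alone; median -0.70, adjusted p = 1.50e-08; adjusted p = 0.107 with an estimated correlation). Lef1 differed by -1.04 ± 0.07 and Ccr7 by -1.06 ± 0.07. TGF-beta response genes had 8 up and 2 down (8 and 2 adjusted over the list alone; median 0.52, adjusted p = 0.000439; adjusted p = 0.153 with an estimated correlation).

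The HIF-1 and hypoxia list was not called (median 0.02, adjusted p = 0.108), though 11 of its 29 members rose and 5 fell (12 and 5 adjusted over the list alone). Hif1a differed by 1.11 ± 0.07, the glucose transporter Slc2a3 by 1.66 ± 0.06 and Pdk1 by -1.09 ± 0.06. Interferon response genes were not called either (median 0.15, adjusted p = 0.448; 6 up and 4 down, the same counts adjusted over the list alone). Their adjusted p was 0.0313 without B6 fusion Tconv replicate 1 and 0.0490 without B6 fusion Treg replicate 2. Nor were helper cytokines and lineage regulators called (median 0.05, adjusted p = 0.155; 6 up and 1 down, 6 and 2 adjusted over the list alone). Of the marker lists of other cell types, that of CD8 T, NK and gamma-delta T cells was lower in Treg (median -0.08, mean -0.53, adjusted p = 0.00782; adjusted p = 0.0526 with an estimated correlation). It had 1 up and 4 down (2 and 4 adjusted over the list alone), and Klrd1 differed by -2.35 ± 0.13. The list for B cells and plasma cells was not called (median -0.04, mean 0.17, adjusted p = 0.544; 2 up, 2 adjusted over the list alone). Neither was that for myeloid cells (median -0.04, adjusted p = 0.448; 1 down, 0 adjusted over the list alone). Dendritic cell and MHC class II markers (median 0.04, adjusted p = 0.616) had 2 up and 1 down (2 and 1 adjusted over the list alone). Red cell and platelet markers (median -0.14, adjusted p = 0.177) had 1 down (1 adjusted over the list alone). Cd74, the invariant chain of MHC class II, was 1.00 ± 0.20 higher in Treg.

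The comparison of the 2 reporter alleles within Treg asked what joining GFP to Foxp3 does to the cells that use it. Averaged over both backgrounds, Prdm1 was 1.01 ± 0.12 higher in fusion Treg (probe set 10368970; adjusted p = 0.000225). The cytokine gene Il10 was higher by 1.09 ± 0.17 (adjusted p = 0.00363), and the inhibitory receptor Tigit by 0.86 ± 0.11 (adjusted p = 0.000651). The costimulatory receptor Icos rose by 0.73 ± 0.11 (adjusted p = 0.00243) and the ubiquitin ligase Nedd4 by 1.01 ± 0.11 (adjusted p = 6.80e-05). Atp6v0d2, a subunit of the vacuolar proton pump, rose by 1.04 ± 0.14 and Neb by 1.02 ± 0.15. Adh1 fell by 0.73 ± 0.10, Lad1 fell by 0.66 ± 0.10 (-1.26 in B6 and -0.07 in NOD) and Neurl3 fell by 0.55 ± 0.09. Foxp3 itself differed by -0.43 ± 0.16 (adjusted p = 0.396), and its 4 fusion arrays, at 11.37 to 11.59, all lay below its 4 ires arrays, at 11.77 to 12.16. Likewise Il2ra (0.13 ± 0.21, adjusted p = 0.989), Ctla4 (0.49 ± 0.16, adjusted p = 0.319) and Ikzf2 (0.28 ± 0.13, adjusted p = 0.628) did not pass the test. Neither did Entpd1 (0.39 ± 0.19, adjusted p = 0.661), Irf4 (0.22 ± 0.13, adjusted p = 0.799) and Hif1a (0.40 ± 0.10, adjusted p = 0.114). Without B6 ires Tconv replicate 1 or 2, each in turn, the adjusted p of Hif1a was 0.0491, and it was 0.0335 with trend and robust variances. With only the Treg groups in the fit, Foxp3 (adjusted p = 0.0342) and Ctla4 (adjusted p = 0.0193) were called.

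In all, 78 genes were called between fusion and ires Treg, 51 higher and 27 lower in fusion, and 64 with 50 higher and 14 lower after centring each array on its median. The count fell to 34 without B6 fusion Treg replicate 1, and 40 and 46 without NOD fusion Treg replicates 1 and 2. It fell to 42 and 32 without B6 ires Treg replicates 1 and 2, and 30 and 41 without NOD ires Treg replicates 1 and 2. Prdm1, Tigit, Icos, Nedd4, Atp6v0d2, Neb, Adh1, Lad1 and Neurl3 were called whichever array was left out, and Il10 had an adjusted p of 0.0517 without B6 fusion Treg replicate 1 and of 0.125 with quantile normalization.

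Of the 25 effector Treg and IRF4-linked genes, 9 were higher and 1 lower in fusion Treg, and 15 and 1 adjusted over the list alone. The median was 0.48 (adjusted p = 4.70e-22; adjusted p = 0.0131 with an estimated correlation). This list was drawn up with knowledge that IRF4 had been of interest in this line, so its direction is not independent evidence. Prdm1, Tigit, Icos and Il10 were among the 9. Of 30 cell cycle genes 1 rose, and 13 rose adjusted over the list alone (median 0.26, adjusted p = 4.85e-15; adjusted p = 0.104 with an estimated correlation). Tconv-high genes had a median of -0.28 with 1 up and 2 down (1 and 8 adjusted over the list alone; adjusted p = 1.45e-08; adjusted p = 0.115 with an estimated correlation). Naive and central T cell genes had a median of -0.23 (camera adjusted p = 0.0039, and 0.485 with an estimated correlation). Their 2 called genes were up, against the list's direction, and adjusted over the list alone 2 were up and 6 down. Idd region genes had 3 up, among them Icos and the complement regulator Cd55 (0.76 ± 0.12, the mean of 1.84 in B6 and -0.32 in NOD), and 6 adjusted over the list alone (median 0.17, adjusted p = 8.51e-08; adjusted p = 0.0524 with an estimated correlation).

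Treg-high genes had 5 up and 1 down (8 and 4 adjusted over the list alone; median 0.13, adjusted p = 0.00141; adjusted p = 0.322 with an estimated correlation). No interferon response gene was called (0 adjusted over the list alone). The list had a median of 0.23 (adjusted p = 2.21e-07; adjusted p = 0.485 with an estimated correlation), with an adjusted p of 0.538 without B6 fusion Treg replicate 1. In B6 alone that list had a median of 0.20 (adjusted p = 0.00596; adjusted p = 0.631 with an estimated correlation). It was -0.16 (adjusted p = 0.0424) without B6 fusion Treg replicate 1 and 0.10 (adjusted p = 0.358) without B6 ires Treg replicate 1. Of 29 HIF-1 and hypoxia genes none was called and 1 rose adjusted over the list alone (median 0.02, adjusted p = 0.431). Immediate-early genes had a median of -0.07 with 1 down (1 adjusted over the list alone; adjusted p = 0.0200; adjusted p = 0.485 with an estimated correlation). Their adjusted p was 0.277 without B6 fusion Treg replicate 1 and 0.409 without NOD fusion Treg replicate 1, and they were not called without NOD ires Treg replicate 1 either. Among markers of other cell types, those of CD8 T, NK and gamma-delta T cells had a median of -0.12 with 0 called and 0 adjusted over the list alone (adjusted p = 0.00739; adjusted p = 0.0914 with an estimated correlation).

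**Figure D2:**
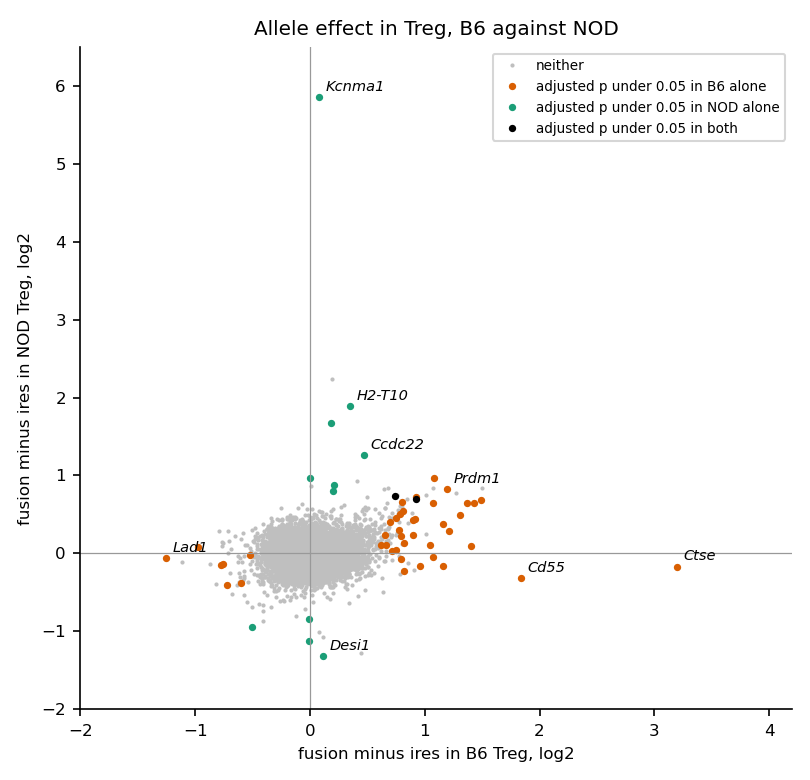
Log2 difference between fusion and ires Treg in B6 (horizontal) and in NOD (vertical), with 1 point per tested gene, coloured by where the gene was called. Kcnma1 stands at 5.86 in NOD and 0.08 in B6, Ctse at 3.20 in B6 and -0.17 in NOD, and 2 genes were called in both.

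The alleles were also compared within each background. In B6 Treg, Ctse, the protease cathepsin E (probe set 10349648), was higher in fusion by 3.20 ± 0.16 (adjusted p = 2.28e-09), Cd55 by 1.84 ± 0.18, and Il10 by 1.49 ± 0.24. Atp6v0d2 was higher by 1.43 ± 0.19, Snrpe by 1.41 ± 0.17, Nedd4 by 1.37 ± 0.15, Prdm1 by 1.20 ± 0.17 and Tigit by 1.08 ± 0.16. Lad1 fell by 1.26 ± 0.14. Without B6 fusion Treg replicate 1 the adjusted p was 0.139 for Il10 and 0.0634 for Tigit, and without replicate 2 it was 0.0657 for Atp6v0d2, 0.0569 for Tigit and 0.0564 for Prdm1. Without B6 ires Treg replicate 2 it was 0.199 for Il10 and 0.0883 for Prdm1. In NOD Treg, the potassium channel gene Kcnma1 (probe set 10582545) was higher in fusion by 5.86 ± 0.24 (adjusted p = 6.51e-11) and Ccdc22 by 1.26 ± 0.13. The Kcnma1 difference rests on this probe set alone, since another, dim at a mean of 4.66, differed by -0.01. The genes of class I antigen presentation H2-M3, Tap1 and Psmb9 were higher in fusion by 0.97 ± 0.13, 0.88 ± 0.13 and 0.80 ± 0.13. It was the NOD ires Treg arrays that stood apart, with Tap1 at 9.61 and 9.92 against 10.69 and 10.60 in NOD fusion and 10.59 to 10.84 in B6 Treg. H2-M3 was at 7.60 and 7.68 there, against 8.71 and 8.51 in NOD fusion and 8.21 to 8.48 in B6 Treg. No list of class I genes was tested. Desi1 fell by 1.32 ± 0.15. With only the NOD Treg groups in the fit, adjusted p was 0.0829 for H2-M3, 0.147 for Tap1 and Psmb9, and 0.0794 for Desi1. H2-M3, Tap1 and Psmb9 had adjusted p of 0.0936, 0.136 and 0.170 without NOD fusion Treg replicate 1 and of 0.0564, 0.175 and 0.253 without NOD ires Treg replicate 1, and Psmb9 0.0787 without NOD fusion Treg replicate 2. Prdm1 differed by 0.82 ± 0.17 in NOD (adjusted p = 0.0877), with an adjusted p of 0.0357 without NOD fusion Tconv replicate 1 or 2 and of 0.0460 without B6 ires Treg replicate 1 or 2, each in turn.

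In B6, 44 genes were called, 37 higher and 7 lower in fusion, and 26 higher and 10 lower after quantile normalization. In NOD, 13 were called, 9 higher and 4 lower. With only the groups compared in the fit, the counts were 168 in B6 and 2 in NOD. Of the 44, 36 had the same sign in NOD, and of the 13, 12 had the same sign in B6. The 2 genes called in both were Gm7265 and Rapgef5, both higher in fusion, where independent lists would share 0.026. Across the 12798 genes, which are not independent replicates, the allele effects in B6 and NOD had r = 0.0668 and a Spearman rho of -0.0437. Without B6 fusion Treg replicates 1 and 2 in turn r was -0.122 and 0.285, without NOD fusion Treg replicates 1 and 2 it was 0.236 and -0.0963, and without NOD ires Treg replicate 1 it was -0.0525. The B6 count was 13 and 14 without B6 fusion Treg replicates 1 and 2 and 11 without B6 ires Treg replicate 2. The NOD count was 4 and 8 without NOD fusion Treg replicates 1 and 2 and 3 without NOD ires Treg replicate 1. H2-T10 (1.89 ± 0.34) and H2-Q5 (1.67 ± 0.29), called in NOD, lost the call without NOD ires Treg replicate 1 and differed by 1.15 and 1.09 then (adjusted p = 0.545 for both). Without either B6 fusion or either NOD fusion Treg array their adjusted p lay between 0.0612 and 0.274. The 2 NOD ires Treg arrays differed from each other, at 7.69 and 9.17 for H2-T10, where B6 ires Treg stood at 9.14 and 9.19, and at 7.15 and 8.32 for H2-Q5.

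The effector Treg and IRF4-linked genes had a median of 0.66 in B6 (5 up and 0 down, 18 and 1 adjusted over the list alone; adjusted p = 2.97e-18; adjusted p = 0.0240 with an estimated correlation). In NOD the median was 0.35 (0 called, 9 up and 1 down adjusted over the list alone; adjusted p = 5.20e-08; adjusted p = 0.239 with an estimated correlation). The cell cycle genes had a median of 0.30 in B6 (1 up, 8 adjusted over the list alone; adjusted p = 1.11e-11; adjusted p = 0.183 with an estimated correlation). Their median was 0.16 in NOD (0 called, 0 adjusted over the list alone; adjusted p = 1.75e-05; adjusted p = 0.510 with an estimated correlation).

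The test of the difference itself, the allele effect in NOD minus that in B6, called 5 genes. Kcnma1 (5.78 ± 0.34, adjusted p = 3.07e-08) and Lad1 (1.19 ± 0.19, adjusted p = 0.0212) were higher. Ctse (-3.37 ± 0.23, adjusted p = 1.60e-07), Cd55 (-2.15 ± 0.25, adjusted p = 0.000385) and Desi1 (-1.44 ± 0.21, adjusted p = 0.00554) were lower. The effector list had a median of -0.27 with 0 genes called and 0 adjusted over the list alone (adjusted p = 0.00143; adjusted p = 0.729 with an estimated correlation). Its adjusted p was 0.0678 without B6 fusion Treg replicate 1, 0.0830 without NOD fusion Treg replicate 2 and 0.167 without B6 ires Treg replicate 2. The count was 3 without B6 fusion Treg replicate 2 and 8 without NOD fusion Treg replicate 2, and Kcnma1, Ctse and Cd55 were called whichever array was left out. Desi1 had an adjusted p of 0.109 without B6 fusion Treg replicate 2. Lad1 had an adjusted p between 0.0668 and 0.160 without either B6 fusion, either B6 ires, the first NOD fusion or the second NOD ires Treg array. Centring the arrays on their medians shifted the median of all genes in this contrast to -0.13 from -0.04, so differences of that size have no settled sign.

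The same alleles were compared in Tconv, in which Foxp3 lay between 7.01 and 8.18 and differed between the alleles by -0.05 ± 0.16 (adjusted p = 0.999). Kcnma1 was higher in fusion Tconv by 3.28 ± 0.17 on average (adjusted p = 3.53e-09), made of 6.30 ± 0.24 in NOD and 0.27 ± 0.24 in B6 (adjusted p = 1). Desi1 fell by 0.67 ± 0.10 (adjusted p = 0.0184), made of -1.28 ± 0.15 in NOD and -0.06 ± 0.15 in B6. Ctse, a gene named here after its values were seen, was also called, higher by 3.41 ± 0.16 in B6 and different by -0.14 ± 0.16 in NOD. Snrpe was higher by 1.41 ± 0.17 in B6 Tconv (adjusted p = 0.000769). Prdm1 (-0.05 ± 0.12, adjusted p = 0.999), Irf4 (-0.19 ± 0.13, adjusted p = 0.999) and Hif1a (0.05 ± 0.10, adjusted p = 0.999) were not called. A second, dim probe set of Kcnma1, with a mean of 4.66, differed by -0.01 between the alleles in NOD Treg and by 0.04 in Tconv. Whether the signal of the brighter probe set comes from Kcnma1 was not examined.

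The 3 genes were 2 higher and 1 lower in fusion, and the count was 5 without B6 fusion Tconv replicate 2 and 12 without NOD ires Tconv replicate 2. Desi1 had an adjusted p of 0.151 without B6 fusion Tconv replicate 1, 0.145 without NOD fusion Tconv replicate 2, 0.0895 without B6 ires Tconv replicate 2 and 0.107 without NOD ires Tconv replicate 1. Of the 13 genes called in NOD Treg, 6 were called in NOD Tconv with the same sign, Desi1, H2-M3, H2-Q5, Kcnma1, Tap1 and Vat1, and of the 44 called in B6 Treg, 2 were called in B6 Tconv, Ctse and Snrpe. The interferon response genes had a median of 0.30 in fusion Tconv (0 called, 0 adjusted over the list alone; adjusted p = 5.89e-17; adjusted p = 0.713 with an estimated correlation), beside 0.23 in Treg. The cell cycle genes had a median of -0.11 (0 called, 0 adjusted over the list alone; adjusted p = 4.46e-07; adjusted p = 0.713 with an estimated correlation). The effector Treg and IRF4-linked genes had a median of -0.08 (0 called, 1 down adjusted over the list alone; adjusted p = 0.0140; adjusted p = 0.713 with an estimated correlation). Their adjusted p was 0.298 without B6 fusion Tconv replicate 1, 0.0728 without NOD fusion Tconv replicate 2, 0.385 without B6 ires Tconv replicate 2 and 0.364 without NOD ires Tconv replicate 1.

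Whether the allele effect differed between the cell types was tested as the effect in Treg minus that in Tconv. All 6 genes called were higher. Nedd4 differed by 1.32 ± 0.15 (adjusted p = 0.00113), the chemokine receptor Ccr4 by 1.25 ± 0.19 and Prdm1 by 1.06 ± 0.17. Ccdc22 differed by 1.01 ± 0.13 (adjusted p = 0.00168), the transcription factor Ahr by 0.91 ± 0.14 and Rapgef5 by 0.79 ± 0.13. Ccdc22 lies on chromosome X, and how near it lies to the altered Foxp3 gene was not examined. Its difference therefore cannot be read as a response to the fusion protein. The effector Treg and IRF4-linked genes had a median of 0.52 (2 up and 0 down, 15 and 1 adjusted over the list alone; adjusted p = 7.40e-28; adjusted p = 0.00602 with an estimated correlation). The cell cycle genes had a median of 0.39 (0 called, 15 up adjusted over the list alone; adjusted p = 7.76e-26; adjusted p = 0.0542 with an estimated correlation).

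Of the 6 genes, Nedd4 and Ccdc22 were called whichever array was left out. The count was 2 without B6 fusion Treg replicate 2, B6 ires Treg replicate 2 or B6 ires Tconv replicate 2, each in turn, when the other 4 genes had adjusted p between 0.0526 and 0.0915. Without B6 fusion Treg replicate 1 the adjusted p was 0.0593 for Ccr4 and Prdm1 and 0.0633 for Rapgef5, and without NOD fusion Tconv replicate 2 it was 0.0537 for Ahr and 0.0713 for Rapgef5. Rapgef5 had 0.0853 without NOD fusion Treg replicate 1 and 0.0741 without NOD ires Treg replicate 2. The count was 18 without B6 fusion Tconv replicate 2, 13 and 12 without NOD ires Tconv replicates 1 and 2, and 14 without B6 ires Treg replicate 1. The fall in Ccr4 in fusion Tconv, -0.77 ± 0.19 in B6 and -0.76 ± 0.19 in NOD, was itself not called (adjusted p = 0.662 and 0.574).

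**Figure D3:**
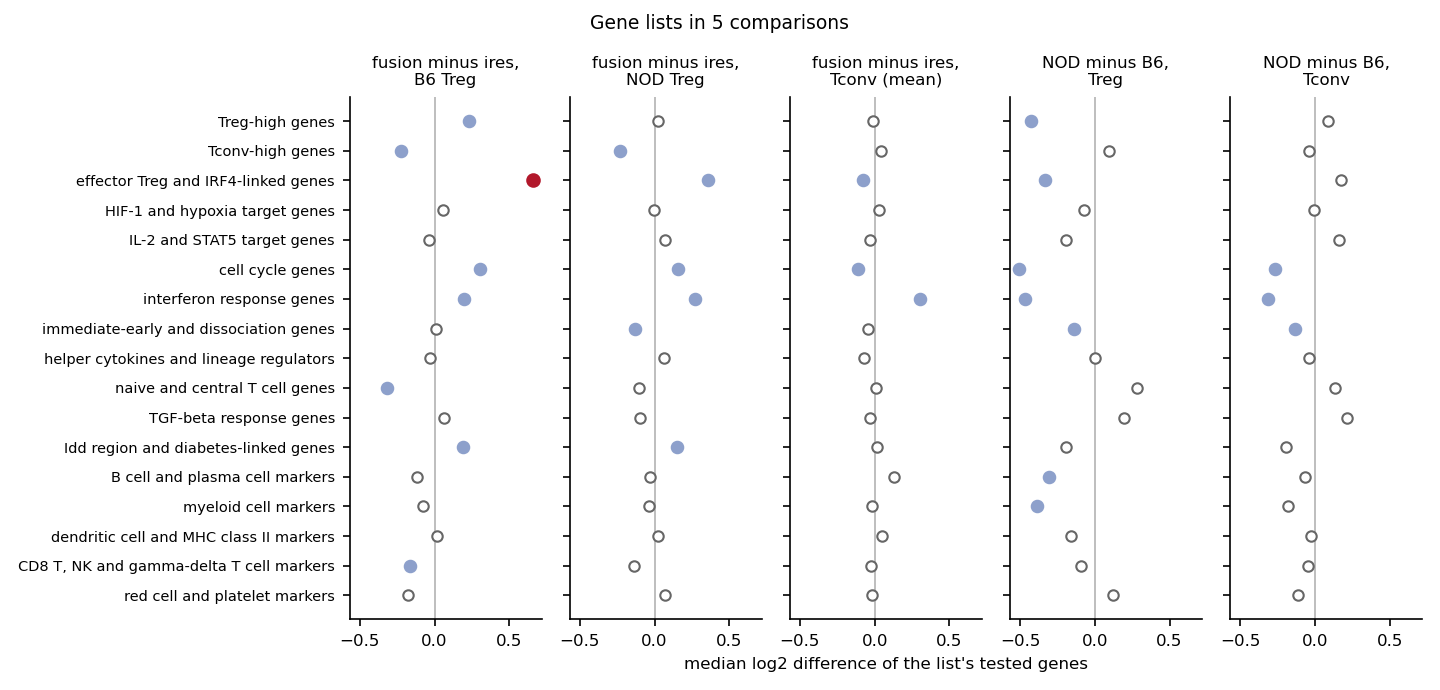
Median log2 difference of the tested genes of each of the 17 gene lists in 5 comparisons, fusion minus ires or NOD minus B6. Open points were not called by camera, blue points were called with the preset correlation alone, and red points with an estimated correlation as well, which here is the effector list in B6 Treg, at 0.66.

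The backgrounds were compared within Treg, over both alleles, to ask how Treg of the diabetes-prone strain differ. Zfp979 (probe set 10518358) was higher in NOD by 4.53 ± 0.14 (adjusted p = 3.22e-13), BC018473 by 3.71 ± 0.15, and Ehd3 by 2.44 ± 0.12. The inflammasome sensor Nlrp1a rose by 2.40 ± 0.11 and H60b, a ligand of the NKG2D receptor, by 2.27 ± 0.15. Trim12a (probe set 10566326) was lower by -4.72 ± 0.18 (adjusted p = 4.19e-12), the interferon-inducible gene Ifi206 by -2.85 ± 0.22 and the glutathione transferase Gsta4 by -2.52 ± 0.12. Hopx differed by -2.21 ± 0.11, Cd72 by -2.10 ± 0.12 and the retroviral restriction factor Apobec3 by -2.10 ± 0.09. A second probe set of Apobec3, with a mean of 7.935, differed by -1.46. The array was designed on a reference sequence, and sequence differences of NOD under its probes were not analysed here. Foxp3 (0.14 ± 0.16, adjusted p = 0.525), Il2ra (-0.17 ± 0.21, adjusted p = 0.594), Irf4 (-0.13 ± 0.13, adjusted p = 0.478) and Prdm1 (-0.15 ± 0.12, adjusted p = 0.390) were not called between the backgrounds.

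Of 12798 genes, 2690 were called, 1433 higher and 1257 lower in NOD Treg, and 1647 higher and 759 lower after centring each array on its median. More were lower than higher with each array's interquartile range as a covariate (1071 higher, 1403 lower) and with every probe set (1780 and 2080), so which side holds more is not settled. The count was 1640 without B6 fusion Treg replicate 1 (729 higher, 911 lower), 1744 without NOD fusion Treg replicate 2 and 1597 without B6 ires Treg replicate 2. Of 30 cell cycle genes 23 fell and none rose (25 down adjusted over the list alone), with a median of -0.51 (adjusted p = 1.48e-11; adjusted p = 0.233 with an estimated correlation). Bub1b fell by 0.99 ± 0.14, Rrm2 fell by 0.87 ± 0.14 and Stmn1 fell by 0.77 ± 0.11. Of 35 Treg-high genes 20 fell and 3 rose (22 and 5 adjusted over the list alone), with a median of -0.43 (adjusted p = 1.08e-05; adjusted p = 0.233 with an estimated correlation). Capg fell by 1.53 ± 0.10, Lrrc32 fell by 1.04 ± 0.12, Tnfrsf9 fell by 0.72 ± 0.09 and Swap70 fell by 0.51 ± 0.08. Of 25 effector Treg and IRF4-linked genes, 11 of them shared with the Treg-high list, 13 fell and none rose (13 adjusted over the list alone; median -0.33, adjusted p = 5.30e-06; adjusted p = 0.233 with an estimated correlation). Ccr8 differed by -0.77 ± 0.12 and Ccr4 by -0.82 ± 0.14.

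Of 26 interferon response genes 9 fell in NOD Treg (9 adjusted over the list alone; median -0.47, adjusted p = 5.29e-05; adjusted p = 0.544 with an estimated correlation). Ifi27l2a differed by -0.81 ± 0.18, Isg20 by -0.68 ± 0.15 and Bst2 by -0.63 ± 0.14. HIF-1 and hypoxia genes had 6 up and 6 down (6 and 8 adjusted over the list alone; median -0.07, adjusted p = 0.483). Pdk1 was lower by -1.85 ± 0.08 while Ndrg1 was higher by 0.75 ± 0.10. Immediate-early genes, which cell isolation can induce among other causes, had 4 down (4 adjusted over the list alone, median -0.14, adjusted p = 0.0465, and 0.544 with an estimated correlation). Their adjusted p was between 0.0503 and 0.205 without either B6 ires Tconv, the second B6 fusion, the first NOD fusion or the second NOD ires Treg array, and 0.0561 with the stricter filter. Markers of myeloid cells had 5 of 9 down (6 adjusted over the list alone; median -0.39, adjusted p = 0.00504; adjusted p = 0.261 with an estimated correlation), with C1qb at -0.51 ± 0.11. Markers of B cells and plasma cells had 2 of 6 down (4 adjusted over the list alone; median -0.30, adjusted p = 0.0111; adjusted p = 0.416 with an estimated correlation), with Cd72 and Blk (-0.39 ± 0.08) passing. Cd74 was lower by -1.01 ± 0.29 (adjusted p = 0.0188), and its adjusted p was 0.0925 without B6 fusion Treg replicate 2, the array with its highest value, 8.63. It was 0.0638 without NOD fusion Treg replicate 2, 0.0561 without B6 ires Treg replicate 1 and 0.0534 without NOD ires Treg replicate 1.

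**Figure D4:**
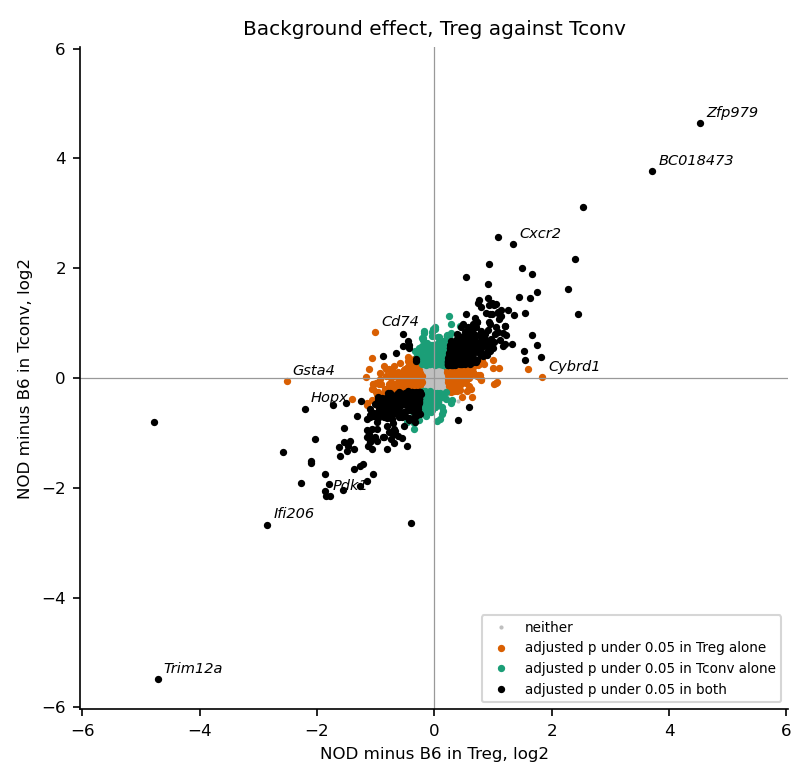
Log2 difference between NOD and B6 in Treg (horizontal) and in Tconv (vertical), with 1 point per tested gene, coloured by where the gene was called. Zfp979 and BC018473 stand high and Trim12a and Ifi206 low in both cell types, while Gsta4 stands at -2.52 in Treg and -0.06 in Tconv.

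The same comparison in Tconv gave Zfp979 at 4.64 ± 0.14, BC018473 at 3.77 ± 0.16, St6galnac2 at 2.57 ± 0.14, the chemokine receptor Cxcr2 at 2.44 ± 0.14 and Nlrp1a at 2.16 ± 0.11, all of them higher in NOD cells. Trim12a was lower by -5.48 ± 0.18, Ifi206 by -2.67 ± 0.22, Pdk1 by -2.16 ± 0.08 and Acadl, of fatty acid oxidation, by -1.97 ± 0.12. Of 35 Treg-high genes 8 rose and 4 fell in NOD Tconv (9 and 4 adjusted over the list alone), and the list was not called (median 0.08, adjusted p = 0.281). It was called without the filter on dim genes (adjusted p = 0.0373). Tnfrsf18 rose by 0.73 ± 0.08 (adjusted p = 1.03e-05), Tnfrsf4 by 0.55 ± 0.10 and Ikzf2 by 0.61 ± 0.13. Foxp3 was higher by 0.50 ± 0.16 (adjusted p = 0.0391). Its adjusted p was 0.198 without NOD fusion Tconv replicate 2, on which it stood at 8.18. It lay between 0.0501 and 0.0974 without either B6 fusion Tconv, either NOD ires Tconv, the second B6 ires Tconv or either B6 fusion Treg array, each in turn. Pdcd1, which encodes the receptor PD-1, rose by 0.82 ± 0.11 and Lag3 by 0.53 ± 0.11. With each array's interquartile range as a covariate adjusted p was 0.101 for Ikzf2 and 0.0556 for Lag3.

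In Tconv 2033 genes were called, 1202 higher and 831 lower in NOD, and 1932 higher and 374 lower after centring each array on its median, which moved the median of all genes to 0.10 from 0.02. With each array's interquartile range as a covariate the excess turned, with 335 higher and 417 lower. The count was 894 without B6 fusion Tconv replicate 1, 911 without NOD fusion Tconv replicate 2, 1030 without B6 ires Tconv replicate 1 and 841 without NOD ires Tconv replicate 1. NOD fusion Tconv replicate 1 carried markers of other cells above every other Tconv array, with Cd74 at 8.27, H2-Aa at 7.33 and Ms4a1 at 5.75, and without it 1901 genes were called, 1079 higher and 822 lower. Cell cycle genes had 1 up and 8 down (4 and 15 adjusted over the list alone; median -0.27, adjusted p = 0.00236; adjusted p = 0.737 with an estimated correlation). Their adjusted p was 0.0609 without B6 fusion Tconv replicate 2. Interferon response genes had 3 down (1 up and 7 down adjusted over the list alone; median -0.31, adjusted p = 0.00201; adjusted p = 0.797 with an estimated correlation). For these it was 0.228 without B6 fusion Tconv replicate 1 and 0.0550 without B6 ires Tconv replicate 2. Immediate-early genes had 1 up and 8 down (1 and 8 adjusted over the list alone; median -0.14, adjusted p = 0.0183; adjusted p = 0.737 with an estimated correlation). It was 0.0689 without B6 fusion Tconv replicate 2 and 0.101 without B6 ires Tconv replicate 2. Across all tested genes the background effects in Treg and Tconv had r = 0.736 and a Spearman rho of 0.705, and 649 genes were called higher in both and 392 lower in both, where independent lists would share 135 and 81.6.

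The background effect in Treg minus that in Tconv was called for 105 genes, 32 higher and 73 lower. Cybrd1 was the highest of the named genes at 1.82 ± 0.18 (adjusted p = 1.88e-05), followed by Atrnl1 at 1.43 ± 0.13, Tex35 at 1.43 ± 0.17 and Ehd3 at 1.28 ± 0.17. Gsta4 was the lowest at -2.46 ± 0.17 (adjusted p = 8.98e-08), with Hopx at -1.66 ± 0.16 and St6galnac2 at -1.49 ± 0.20. Of the Treg-high genes 8 were lower and none higher (18 and 1 adjusted over the list alone), with a median of -0.45 (adjusted p = 7.38e-15; adjusted p = 0.0289 with an estimated correlation). Tnfrsf18 differed by -0.94 ± 0.12, Tnfrsf4 by -0.97 ± 0.13 and Lrrc32 by -0.93 ± 0.17. Of the effector Treg and IRF4-linked genes 7 were lower and none higher (18 and 0 adjusted over the list alone), with a median of -0.52 (adjusted p = 4.56e-17; adjusted p = 0.0289 with an estimated correlation). Pdcd1 differed by -1.01 ± 0.16 and Ccr8 by -0.94 ± 0.17. IL-2 and STAT5 target genes had 2 lower (3 adjusted over the list alone; median -0.30, adjusted p = 1.21e-06; adjusted p = 0.135 with an estimated correlation), Tnfrsf18 among them. Cell cycle genes had a median of -0.29 with 0 called (1 down adjusted over the list alone, camera adjusted p = 1.03e-08, and 0.315 with an estimated correlation). The count was 69 without B6 fusion Tconv replicate 1 and 87 without NOD fusion Tconv replicate 1, the array with raised markers of other cells.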

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

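The tests of runs of neighbouring genes, of calls per chromosome, of RNA from other cells, of run members, of cell shares and of sequence variants were chosen after the result was seen, except that the test of uncalled genes in the B6 run was set before its value was known, as were the interquartile range test and the other splits of the samples.

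The allele effect in Treg differed between the backgrounds, by a test of the difference, for 5 genes. NOD minus B6 was 5.78 for Kcnma1, -3.37 for Ctse, -2.15 for Cd55, -1.44 for Desi1 and 1.19 for Lad1. Of the 17 lists 3 were called in this contrast, none of them with an estimated correlation. Some of the genes called in 1 background lie near each other. The longest run in B6 Treg held 3 of 43 called genes with known positions, Cd55, Il10 and Ctse on chromosome 1, each within 20 tested genes of the next. Random sets of genes gave a run as long with a permutation p = 0.146. Kif15, Lztfl1 and Ccr9 on chromosome 9 made a run of the same length. Further calls on chromosome 1, Snrpe, Ptprv and Lad1, stood at places 444, 459 and 472 among its tested genes. With Ctse at 421 they fell just outside the window, and a wider window was not tested. The run test therefore cannot tell whether the calls from Cd55 to Lad1 lie together by chance. The longest run in NOD Treg held 2 of 12, Psmb9 and Tap1 on chromosome 17 (permutation p = 0.188). With the window of 20, neither run was longer than chance can give. The NOD calls were nevertheless uneven over the chromosomes. Chromosome 17 held 5 of the 12, Psmb9, Tap1, H2-Q5, H2-T10 and H2-M3, within 96 tested genes (permutation p = 0.0108). In B6, chromosome 1 held 7 of 43 within 302 tested genes (permutation p = 0.264), all but Icos from Cd55 to Lad1. A count over the whole chromosome does not test that shorter stretch. The calls of all 5 were lost without NOD ires Treg replicate 1, with adjusted p from 0.0564 for H2-M3 to 0.545 for H2-Q5 and H2-T10. Genes of this complex may be regulated together, and then their places are not independent.

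A response to the altered Foxp3 protein inside Treg and DNA of another strain kept around a run in 1 of the lines are candidate explanations for these runs. Against the first, the change in Tconv was 0.874 of that in Treg for the NOD run (median of its genes), although Foxp3 was low in Tconv. For the B6 run the median ratio was 0.404, with 0.0859 for Il10 and 1.07 for Ctse, which leaves that run open. The uncalled genes inside the B6 run stood at percentile 93.3 of stretches of equal length for their change in Tconv, and the NOD run held 0 uncalled genes, so this test leaves the second explanation open for both runs. Of the 5 NOD genes on chromosome 17, Tap1, H2-Q5 and H2-M3 were also called in NOD Tconv. Psmb9 (0.64, adjusted p = 0.122) and H2-T10 were not called there. H2-T10 stood at 7.77 and 8.92 on the NOD ires Tconv arrays, against 10.12 and 10.23 on the NOD fusion ones. DNA of another strain and a shared change in class I genes stay candidate explanations for these 5 genes. Over the other called genes the median ratio was 0.0507 in B6 and 0.790 in NOD.

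The allele effect differed between Treg and Tconv for 6 genes, by 1.32 for Nedd4, 1.01 for Ccdc22, 1.25 for Ccr4, 0.91 for Ahr, 1.06 for Prdm1 and 0.79 for Rapgef5, and for 7 of the 17 lists, of which only 1 stayed called with an estimated correlation. That was the effector Treg and IRF4-linked list, with a median difference of 0.52 (adjusted p = 0.00602 with an estimated correlation). Since it was drawn up with knowledge of the interest in IRF4 in this line, its direction is not independent evidence. Another of the 7 was the list of B cell and plasma cell markers (median -0.19, adjusted p = 0.00532; adjusted p = 0.282 with an estimated correlation). It was not called without NOD fusion Tconv replicate 1 (median -0.07, adjusted p = 0.294), the array with raised markers of other cells. 3 technical explanations were tested for the higher level of the effector Treg and IRF4-linked list in fusion Treg. Tconv RNA in the ires Treg arrays would raise all Treg genes in fusion. But the 20 genes outside the list with the highest fold between Treg and Tconv had a median allele effect of 0.10 ± 0.06, against 0.48 for the list. This ± is a bootstrap SE over genes and holds no spread between arrays. With each array's interquartile range as a covariate the list's median was 0.49 (adjusted p = 1.95e-17), and without its member in the runs of neighbouring genes it was 0.47 over 24 genes. A larger share of effector or cycling cells among fusion Treg may contribute, since the cell cycle list had a median of 0.26, and cannot be told apart from a change within each cell because each array measures many cells together. An effect of the allele on Treg is the biological explanation that the design names, and it stays a hypothesis.

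The background effect differed between Treg and Tconv for 105 genes, among them Cybrd1 (1.82), Atrnl1 (1.43), Tex35 (1.43), Gsta4 (-2.46), Hopx (-1.66) and Cd74 (-1.85), and for 6 of the 17 lists, of which 2 stayed called with an estimated correlation. On NOD fusion Tconv replicate 1 Cd74 stood at 8.27, against 5.81 to 6.46 on the other Tconv arrays, and without that array the difference was -1.35 (adjusted p = 0.0111). The adjusted p of Cd74 was 0.0347, and lay between 0.0561 and 0.137 without the first B6 fusion, B6 ires or NOD ires Tconv array, the second B6 fusion or NOD fusion Treg array, or any B6 ires or NOD ires Treg array, each in turn. The Treg-high list had a median difference of -0.45 and the effector list of -0.52 (adjusted p = 0.0289 for both with an estimated correlation). Markers of B cells and plasma cells (median -0.21, adjusted p = 0.0204; 0.470 with an estimated correlation) and of dendritic cells and MHC class II (median -0.12, adjusted p = 0.0304; 0.514) were also among the 6. Without NOD fusion Tconv replicate 1 their adjusted p was 0.212 and 0.196. Without other single arrays it reached 0.0952 and 0.266.

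For the Treg-high list, Tconv RNA in the NOD Treg arrays would raise the Tconv-high genes there. These had a median NOD effect of 0.0946 ± 0.194 (for medians, ± is a bootstrap SE over genes, without the spread between arrays). That test has a wide error, and it argues against a share of Tconv RNA only together with Foxp3, which differed by 0.14 ± 0.16 between NOD and B6 Treg. Treg RNA in the NOD Tconv arrays would leave Treg alone unchanged, but the list's median in Treg was -0.43 ± 0.10. On these arrays such RNA would therefore not account for the difference alone. A share of Treg RNA there may still add to it. Foxp3 was 0.50 higher in NOD than in B6 Tconv (adjusted p = 0.0391; 0.198 without NOD fusion Tconv replicate 2, where it stood at 8.18 and Ikzf2 at 8.17). Il2ra was 0.85 higher (adjusted p = 0.0143; 0.0910 without that array and 0.0797 without NOD ires Tconv replicate 1), at 6.82 and 6.94 on those 2 arrays against at most 5.82 in B6 Tconv. Sequence variants under the probes could act on genes seen mainly in Treg, and the 9 members above the median level of all genes in Tconv had a median difference of -0.30 ± 0.18, too few genes to decide. A difference in the state of Treg between the backgrounds stays open as a hypothesis.

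Other splits of the arrays were tried with a simpler fit. For fusion against ires in Treg, 1 of 34 splits, the real one, gave as many calls (67, highest other 1). The same held for NOD against B6 in Treg (1 of 34; 2357 calls, highest other 0) and in Tconv (1 of 34; 2150 calls, highest other 0). Of these 34 splits only 18 hold the other factor equally on both sides, too few for a share under 5%. For Treg against Tconv 1 of 100 splits drawn gave as many (3750 calls, highest other 1). Among 100 splits within the 4 lines it was again only the real one (highest other 855), a share under 5% of those drawn. For fusion against ires in Tconv that fit in limma gave 0 calls and 421 genes at an unadjusted p under 0.05. With 0 calls all 34 splits had to give as many, so chance cannot be excluded and this count says nothing more. The other splits mix real groups, which raises the residual spread and lowers their counts, so the distance to the real count does not measure the evidence. Chance between mice was not covered, since the sources do not say how many mice stood behind the arrays. For the allele effect in Treg minus that in Tconv 2 of 92 splits gave as many as the real 5 calls, with 282 at most. For the background effect 4 of 98 gave as many as the real 117, with 5310 at most. Both shares lay under 5%. Splits with several times the real count point to a structure of the samples, and their make-up was looked up afterwards. The split with 5310 calls set NOD Treg and B6 Tconv arrays against the rest, so that it measured the background effect itself. The others for that contrast, with 1022 and 210 calls, also held unequal numbers of NOD arrays in Treg and Tconv. Since the remaining splits mix real groups, which lowers their counts, the share of 4 of 98 does not exclude chance for the 117. The split with 282 calls held 1 array of each of the 8 groups on either side and so carried no allele difference. It shows a structure between arrays of the same group, whose source was not tested, and for the 5 calls chance is therefore not excluded.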

How the results depend on the processing

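The covariate fit with each array's interquartile range was chosen after the data were seen; the other alternatives were planned. The cause was not tested for any change below, except that leaving out an array lowers the number of arrays, and then the lone array of a group is assumed to vary like the other groups. Signal over background limits the genes tested, since genes at log2 6.06 or under were left out.

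Leaving out each array in turn gave 3242 to 3667 calls for Treg against Tconv, 30 to 91 for fusion against ires in Treg, 11 to 49 in B6 Treg, 3 to 15 in NOD Treg, and 3 to 8 for their difference. It gave 2 to 12 in Tconv, 2 to 18 for the allele effect in Treg minus Tconv, 1597 to 3063 for NOD against B6 in Treg, 841 to 2365 in Tconv and 69 to 141 for their difference. The correlation of the allele effects of B6 and NOD Treg ranged from -0.122 to 0.285, with -0.0963 without NOD fusion Treg replicate 2 and -0.0525 without NOD ires Treg replicate 1, so its sign is not settled.

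The 5 calls for the NOD minus B6 allele effect were 9 with a stricter filter and with trend and robust variances, and 8 with quantile normalization and with only the groups compared. The 3 in Tconv were 6 with trend and robust variances and 5 with the covariate. The 6 for the allele effect in Treg minus Tconv were 10 with quantile normalization, 19 with trend and robust variances and 16 with the covariate. The 44 in B6 Treg were 20 with array weights, 29 with every probe set, 168 with only the groups compared and 29 with the covariate. The 78 over both backgrounds were 46 with every probe set, and the 13 in NOD were 22 with every probe set and 2 with only the groups compared. NOD against B6 in Tconv had 752 calls and the background difference 175 with the covariate. Of 170 list tests 62 were called, 10 with an estimated correlation and 28 with fry.

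The interferon response list changed sign in 3 contrasts. With each array left out in turn it ranged from -0.16 to 0.60 in B6 Treg, the lowest without B6 fusion Treg replicate 1. In NOD minus B6 it ranged from -0.36 to 0.38, the lowest without B6 fusion Treg replicate 2, and stood at -0.25 with the covariate. In Treg minus Tconv it ranged from -0.25 to 0.16, with 0.16 without B6 fusion Tconv replicate 1 and 0.15 without B6 fusion Treg replicate 2.

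Over the genes named, no call changed direction. With arrays left out in turn, 3424 comparisons kept their side of the threshold, 131 lost the call and 13 gained it. Under the other alternatives 2373 kept it, 59 lost the call and 12 gained it.

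The replicate numbers were not taken to pair the samples, though pairing is not ruled out. In NOD ires, H2-Q4, H2-Q5 and H2-T10 were lower on replicate 1 than on replicate 2 in both cell types. Deviations of Treg and Tconv arrays of the same line correlated between 0.0803 and 0.398, 3 of 4 over 0.1, and those of all 28 pairs of groups between -0.371 and 0.465, 16 of them over 0.1. With the replicate number as a block the allele effect in Treg minus Tconv had 16 calls. With line and number as a block it had 31, and the background difference 258.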

Other observations

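The genes below were chosen after their values were seen, and no test was planned for them.

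The 2 NOD ires arrays of each cell type differed from each other in class I genes of the major histocompatibility complex, replicate 1 being the lower. H2-Q4 was at 8.16 and 10.04 on NOD ires Treg replicates 1 and 2, and at 7.87 and 9.45 on the Tconv replicates. H2-T10 was at 7.69 and 9.17 in Treg and at 7.77 and 8.92 in Tconv. H2-Q5 was at 7.15 and 8.32 in Treg and at 6.83 and 7.76 in Tconv.

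NOD fusion Tconv replicate 1 carried Cd79a at 5.93 and H2-Ab1 at 7.21, above the other 15 arrays.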
